A study of Mus musculus with 7 samples.

How the data were processed

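Tumour-associated macrophages were sorted on CD11b, the integrin alpha M chain encoded by Itgam, from dissociated orthotopic T387 glioblastoma xenografts grown in the brains of NSG mice. NSG mice lack T cells, B cells and NK cells. Pracinostat, a hydroxamate inhibitor of zinc-dependent histone deacetylases, was given by mouth at 30 mg/kg, 4 times a week for 3 weeks, starting on day 7 after implantation. Control mice received the DMSO-containing solvent, per the labels' protocols. The same labels also state 3 mg/kg for the prepared drug, which was read here as a statement on the solution. There were 3 DMSO and 4 Pracinostat samples, which the labels call biological replicates without saying which animals they came from.

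Total RNA libraries were made with a stranded kit for low input (1 ng of RNA) and sequenced as pairs of 150 bases on an Illumina NovaSeq over 2 lanes per sample, per the labels' protocols. The submitters' processing notes name Trim Galore, FastQC, STAR, RSEM, MultiQC and DESeq2, with no versions, roles or order, and the mouse build GRCm39. The annotation and the strand setting of the counting are not given in the sources used here, so counts of antisense and overlapping genes are uncertain. The deposited values are expected counts per gene symbol as RSEM estimates them, stored as whole numbers and not normalized. Of the 25571 rows, 3205 carry an Ensembl identifier in place of a symbol and hold 1.21% of the counts. Mitochondrially encoded genes were not analysed here. Near-identical family members, such as the replication-dependent histones and Bcl2a1a and Bcl2a1d, share reads, so their single values are uncertain. No coordinates are given, because the reference at hand was of another build.

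Differences between Pracinostat and DMSO were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling, filterByExpr with a minimum count of 10, a robust quasi-likelihood fit and a two-sided test. P-values were adjusted by the Benjamini-Hochberg method over the 15822 genes tested, with a threshold of 0.05. Log2 fold changes are Pracinostat minus DMSO and are given ± their standard error, and levels are CPM with TMM-scaled library sizes. Before the data were examined, 42 gene lists were fixed, and the 38 with at least 5 genes tested were compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2). Camera used a preset inter-gene correlation of 0.01, and the p with a correlation estimated for each list is given beside the calls. List members were also adjusted over the list alone. A list score is the mean over members of log2 CPM minus the gene's mean over the 7 libraries. Shares of library counts in 12 classes of other cell types or sample quality, list scores, total counts and genes detected were compared by two-sided exact permutation tests over all 35 splits of the libraries, for which the smallest possible share of splits is 0.0286.

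Genes were named by a rule fixed before the data were examined. It took, where none passed, the 5 genes with the smallest p in each direction among those with an assigned name, a mean log2 CPM of at least 2 and groups that did not overlap, up to 2 members of each list with the smallest p, and 20 genes chosen in advance. Genes named outside the rule are said to be chosen after their values were seen. Unnamed gene models were skipped (2 higher and 2 lower).

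On counts simulated from these libraries' means and spread, with 200 changed genes in each of 3 runs over 15822 genes, the gene test recovered 21.9% of 2-fold, 72.1% of 4-fold and 90.4% of 8-fold changes, and called 0.0329% of unchanged genes. In simulated data a planted list of 32 genes shifted by 0.5 on the log2 scale was called in 20 of 20 runs, and 1 of 740 unchanged lists was called. Changed genes and simulated lists were drawn from genes with a mean log2 CPM of at least 2, so recovery at lower levels was not measured. The simulated genes varied independently, so this does not test the effect of correlated genes. The libraries were also compared in pairs for duplicates, and none were found, with chi-square per degree of freedom at least 30. Alternatives covered the scaling, the low-count filter, DESeq2 1.42.0, limma-voom, leaving out each library, thresholds, the replicate number as a block, an estimated correlation and fry. Those added after the data were seen were leaving out both libraries with the most Col1a1, a fit without robust estimation and camera on voom values.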

Results

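RNA of CD11b-sorted macrophages from glioblastoma xenografts was sequenced in 3 DMSO and 4 Pracinostat libraries. The comparison asks what the gene expression of these cells looked like after weeks of treatment with a histone deacetylase inhibitor, in a study concerned with drugs that enhance phagocytosis. The libraries held 10142753 to 16950597 counts and 16319 to 19244 detected genes. Mean depth was 13530458 ± 2039553 counts (SD, n = 3) with DMSO and 14299098 ± 2920070 counts (SD, n = 4) with Pracinostat (exact permutation p = 0.714). Genes detected averaged 16996 ± 937 (SD, n = 3) and 18499 ± 609 (SD, n = 4), with an exact permutation p of 0.0857. Itgam, which encodes the sorted antigen, stood at 1472 ± 192.4 CPM (SD, n = 3) with DMSO and 1812 ± 521.3 CPM (SD, n = 4) with Pracinostat. Ptprc, the pan-leukocyte marker CD45, stood at 582.4 and 599 CPM.

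No single gene passed the test. Of 15822 genes, 0 had an edgeR adjusted p under 0.05, the smallest being 0.482, and 661 (4.18%) had an unadjusted p under 0.05, of which 444 were higher and 217 lower with Pracinostat. DESeq2 called 27 genes, 25 of them higher, including 9 at 0 in every DMSO library, and limma-voom called 0. Among named genes with a mean log2 CPM of at least 2 and groups that did not overlap, the 5 with the smallest p on the higher side were Nlrp3, the inflammasome sensor (1.04 ± 0.19), Gpr84, a receptor for medium-chain fatty acids (1.24 ± 0.24), Csf1, the macrophage growth factor (1.03 ± 0.21), Ripk2, the kinase downstream of NOD receptors (1.02 ± 0.22), and Tlr2, a receptor for bacterial lipoproteins (0.72 ± 0.16). Nlrp3 stood at 366.5 ± 53.45 CPM (SD, n = 3) with DMSO and 751.6 ± 173.6 CPM (SD, n = 4) with Pracinostat. On the lower side were Ttn (-2.99 ± 0.55), Lrp8, a lipoprotein receptor (-1.02 ± 0.25), R3hcc1 (-1.59 ± 0.40), the lysosomal sulfamidase Sgsh (-1.08 ± 0.28) and Apob (-0.95 ± 0.26), chosen the same way. Lgi2, named after its values were seen, had a smaller p than Ripk2 and Tlr2 but a low level, at 0 CPM in each DMSO library and 4.6 ± 2.86 CPM (SD, n = 4) with Pracinostat. Over all genes tested, 965 (6.1%) had groups that did not overlap, against 5.71% by chance.

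The group with the smallest camera p was inflammatory cytokines and effectors. Of its 32 genes tested, 25 had positive fold changes, with a median of 0.53. By edgeR 0 passed over all genes and 10 were higher when adjusted over the list alone. DESeq2 called 4 members over all genes, Nlrp3 (adjusted p = 0.00225), Il1a (0.00225), Csf1 (0.0084) and Tlr2 (0.013). Beside Nlrp3, Csf1 and Tlr2, the 10 that passed edgeR over the list alone were, named after their values were seen, the cytokines Il1a (1.51 ± 0.35) and Tnf (0.94 ± 0.27), the NF-kappaB inhibitors Tnfaip3 (0.88 ± 0.21) and Nfkbia (0.71 ± 0.18), the interferon regulatory factor Irf1 (0.57 ± 0.16), mitochondrial superoxide dismutase Sod2 (0.60 ± 0.20) and the itaconate enzyme Acod1 (1.02 ± 0.36). Nos2, inducible nitric oxide synthase, went the other way (-1.41 ± 0.54) and did not pass. The list was higher by camera (adjusted p = 7.15e-05), and this call held without any 1 of the libraries. With an estimated correlation the adjusted p was 0.948 (unadjusted p = 0.0252). The list score was -0.314 ± 0.0464 (SD, n = 3) with DMSO and 0.236 ± 0.214 (SD, n = 4) with Pracinostat. It was higher in all 4 Pracinostat libraries than in any DMSO library (exact permutation p = 0.0571, adjusted p = 0.943 over 38 lists). With 38 lists, a lone list at the smallest possible exact p of 0.0286 cannot pass after adjustment, so the adjusted value decides little.

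**Figure D1:**
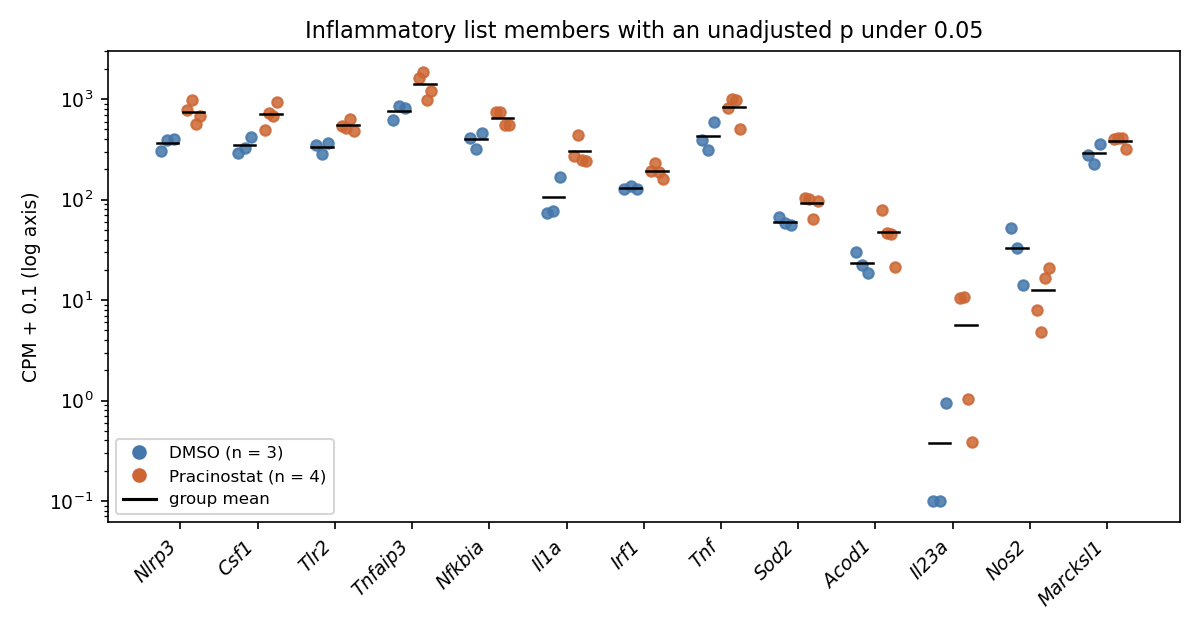
CPM plus 0.1 (log axis) of the 13 inflammatory list members with an unadjusted p under 0.05, per library, with group means as lines (3 DMSO, 4 Pracinostat). Nlrp3 averaged 366.5 CPM with DMSO and 751.6 with Pracinostat, and Nos2 lay lower with Pracinostat.

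Immediate-early and dissociation-response genes, which cells also induce during tissue processing, gave no camera call (adjusted p = 0.0588, and 0.948 with an estimated correlation). Of 26 genes, 23 were positive with a median of 0.17. At the preset correlation the list was called higher with a stricter filter (0.0455), and without DMSO replicate 3 (0.016), Pracinostat replicate 3 (0.000725) or Pracinostat replicate 4 (0.0221). Nfkbiz, an NF-kappaB cofactor (0.71 ± 0.18), passed over the list alone and Egr1 (0.51 ± 0.18) did not. Their share of counts was 1.71 ± 0.207% (SD, n = 3) with DMSO and 2 ± 0.255% (SD, n = 4) with Pracinostat (exact permutation p = 0.2).

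Markers of monocyte-derived macrophages were lower as a group, with 22 of 28 genes negative and a median of -0.35 (camera adjusted p = 0.00169). The members with the smallest p were Mgst1, a microsomal glutathione transferase (-1.77 ± 0.51), and Emilin2 (-0.45 ± 0.18), and 0 passed over the list alone. With an estimated correlation the adjusted p was 0.948. The score of Pracinostat replicate 3 was -1.6, and without that library the adjusted p was 0.304. Without DMSO replicate 1 it was 0.124. The homeostatic microglia list had 19 of 26 genes positive, with a median of 0.20 (camera adjusted p = 0.158, and 0.948 with an estimated correlation). At the preset correlation it was called higher without DMSO replicate 3 (0.0437) or Pracinostat replicate 1 (0.00371), and with camera on voom values (0.0124). Tgfbr1 (0.38 ± 0.15) and Tmem119 (0.54 ± 0.27) were positive and P2ry12, the ADP receptor of microglia, was at -0.01 ± 0.21.

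Alternative activation genes were also lower by camera (adjusted p = 0.0232), with 17 of 28 negative and a median of -0.15. Arg1, the arginine-degrading enzyme, was at -1.66 ± 0.66, from 336.5 ± 169.2 CPM (SD, n = 3) to 106.5 ± 68.87 CPM (SD, n = 4), with overlapping groups. Folr2, a folate receptor of tissue macrophages, was at -0.86 ± 0.35 and Mrc1, the mannose receptor CD206, at -0.58 ± 0.66, and 0 members passed over the list alone. The adjusted p was 0.948 with an estimated correlation, 0.284 without Pracinostat replicate 3, 0.124 without DMSO replicate 1 and 0.0588 without Pracinostat replicate 4. Replication-dependent histone genes were lower by camera (adjusted p = 0.0385; 20 of 27 negative, median -0.25), led by H4c9 (-1.05 ± 0.53) and H4c8 (-1.36 ± 0.69). That call had an adjusted p of 0.948 with an estimated correlation. It held in 3 of the 7 fits that left out a library, the others being 0.52 and 0.149 without Pracinostat replicates 2 and 1, and 0.416 and 0.128 without DMSO replicates 1 and 3.

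**Figure D2:**
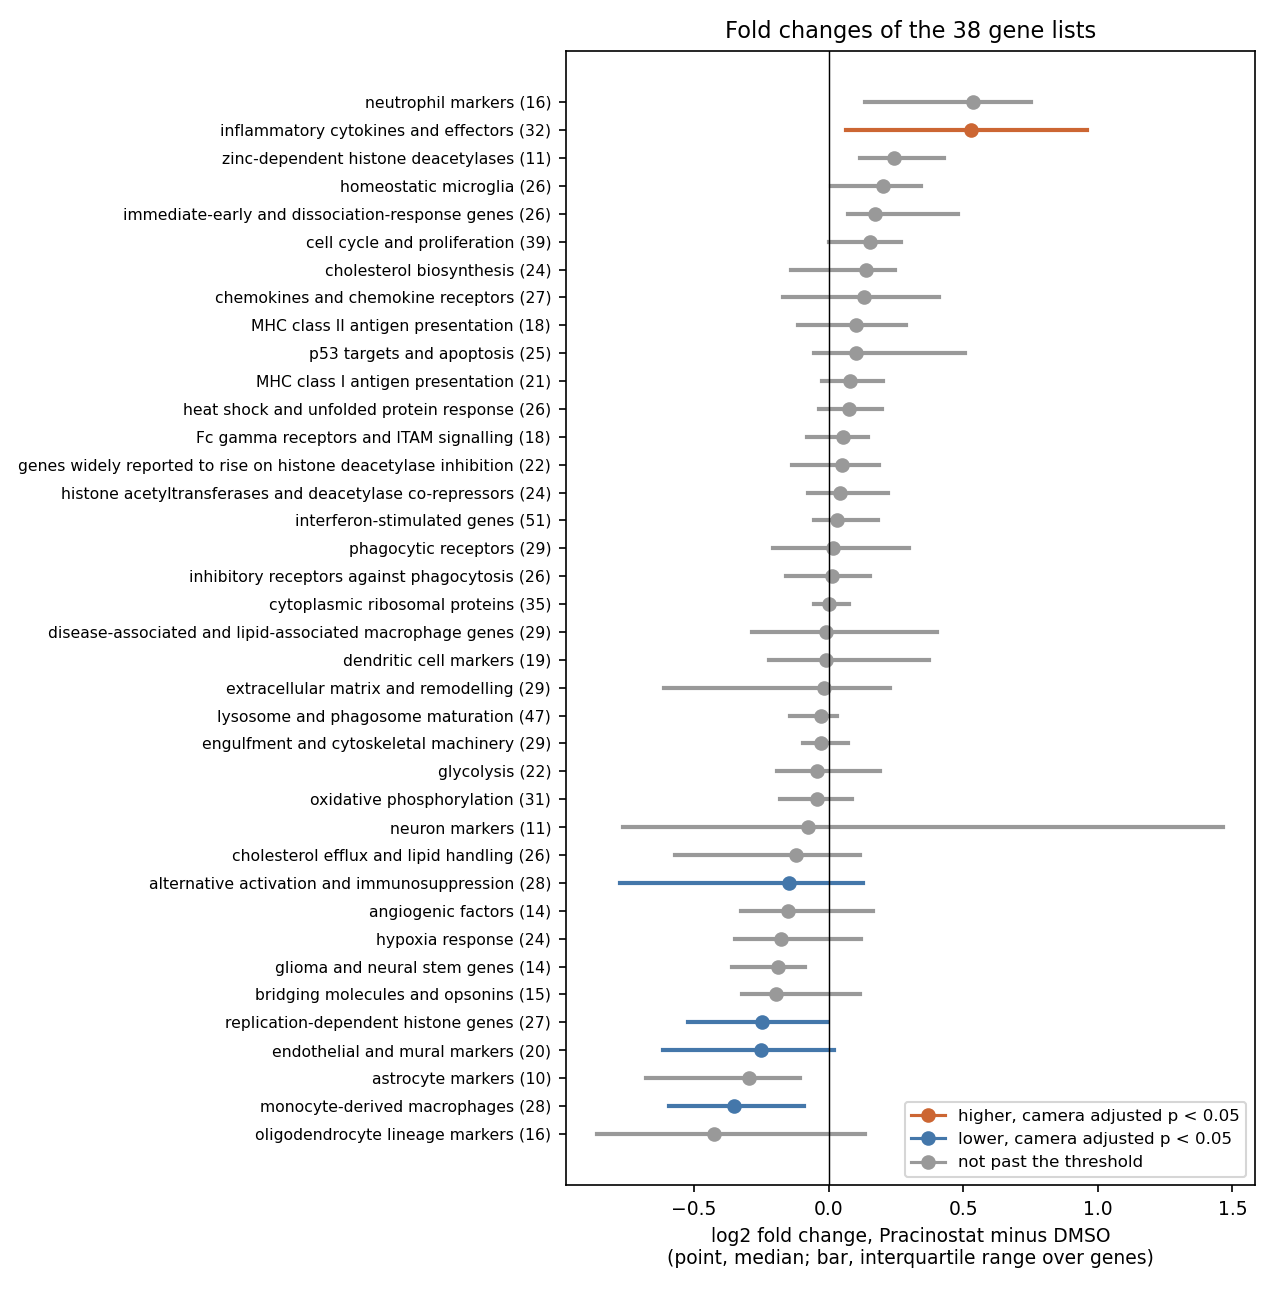
Median log2 fold change (point) and interquartile range over genes (bar) for 38 gene lists, with the number of genes tested in parentheses. The inflammatory list has a median of 0.53 and the monocyte-derived list of -0.35, and coloured lists passed camera at an adjusted p under 0.05.

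Genes of phagocytosis gave no call between the groups. The phagocytic receptors had 16 of 29 genes positive (camera adjusted p = 0.486, direction down, median 0.02). Stab1, a scavenger receptor, was at -0.63 ± 0.17 and Cd14, the lipopolysaccharide co-receptor, at 0.86 ± 0.34. The efferocytosis receptors Mertk and Axl were at 0.00 ± 0.14 and 0.30 ± 0.15, and Trem2 was at -0.14 ± 0.18. The inhibitory receptors had 13 of 26 positive (camera adjusted p = 0.693), with Sirpa, the receptor for the CD47 signal, at 0.04 ± 0.14, Cd300a at -0.69 ± 0.24 and Pirb at -0.68 ± 0.31. Cd47 was at -0.12 ± 0.21 and Cd274, which encodes PD-L1, at 0.13 ± 0.23. Fc gamma receptors (adjusted p = 0.896), engulfment machinery (0.651), bridging molecules (0.466) and lysosomal genes (0.33) gave no camera call. Lysosomal genes were called lower without DMSO replicate 2 (adjusted p = 0.0285). Cd68 was at -0.21 ± 0.22.

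Antigen presentation and interferon genes gave no call either. MHC class II genes had a camera adjusted p of 0.765, with Cd86 at 0.32 ± 0.15 and H2-Ab1 at 0.16 ± 0.68, and MHC class I genes had 0.385, with Psme2 at 0.41 ± 0.17. Of 51 interferon-stimulated genes 32 were positive (0.622), Cxcl10 being at 1.24 ± 0.33 and Ifit3 at -0.06 ± 0.24. In Pracinostat replicate 3, Cxcl10 was at 185 CPM against 72.7 to 86 in the other Pracinostat libraries. Chemokines (0.896) included Ccl22 at 2.59 ± 1.02. Ccl22 was at 44.75 CPM in Pracinostat replicate 2, against 2.18 to 11.1 in the other Pracinostat libraries and 1.12 to 4.87 with DMSO.

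The drug's targets and commonly reported response genes were listed in advance. Of the 11 zinc-dependent deacetylases 9 were positive, with a median of 0.24 (camera adjusted p = 0.186). Hdac2 was at 0.65 ± 0.27, Hdac6 at 0.53 ± 0.28, Hdac1 at 0.40 ± 0.25 and Hdac3 at 0.24 ± 0.25. Acetyltransferases and co-repressors (0.591) included Kat2a at 0.54 ± 0.20. Genes widely reported to rise on deacetylase inhibition had 13 of 22 positive (0.859). Cdkn1a, the cell cycle inhibitor p21, stood at 108.3 ± 12.21 CPM (SD, n = 3) with DMSO and 120.9 ± 40.18 CPM (SD, n = 4) with Pracinostat (0.16 ± 0.24), and Gadd45b was at 0.57 ± 0.20.

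Among metabolic groups, camera made no call for cholesterol efflux and lipid handling (adjusted p = 0.15; Acaca 0.70 ± 0.24, Lipa -0.45 ± 0.20), hypoxia response (0.186; Ndrg1 -0.77 ± 0.21), glycolysis (0.486; Slc16a1 -0.46 ± 0.23), oxidative phosphorylation (0.381; Cox5b -0.62 ± 0.20) or cholesterol biosynthesis (0.961; Pmvk 0.87 ± 0.38). Calls appeared when 1 library was left out, and lipid handling was called lower with camera on voom values (0.0279). Without Pracinostat replicate 1, lipid handling (0.00951) and hypoxia genes (0.0446) were lower, and without DMSO replicate 2 oxidative phosphorylation was lower (0.0235). All 7 libraries also gave no call for p53 targets and apoptosis (0.33; higher without Pracinostat replicate 3, 0.0163), where the survival genes Bcl2a1a and Bcl2a1d were at 1.47 ± 0.44 and 1.07 ± 0.31, and for heat shock and unfolded protein genes (0.33; Dnajb1 0.63 ± 0.18).

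Markers of other mouse cells were low. Endothelial and mural markers were lower by camera (adjusted p = 0.0114; 14 of 20 negative, median -0.25), with Rgs5 at -0.91 ± 0.47 and Pecam1 at -0.48 ± 0.30. The adjusted p was 0.948 with an estimated correlation, and 0.124, 0.13 and 0.102 without DMSO replicate 1, DMSO replicate 2 and Pracinostat replicate 4. These markers held 0.0457 ± 0.00842% of counts (SD, n = 3) with DMSO and 0.0356 ± 0.0168% (SD, n = 4) with Pracinostat (exact permutation p = 0.429). Oligodendrocyte markers held 0.0433 ± 0.00315% (SD, n = 3) and 0.0723 ± 0.0362% (SD, n = 4), with an exact permutation p of 0.171. That share was 0.124% in Pracinostat replicate 1 and 0.0403 to 0.0694% in the other libraries. Few abundant members weigh on this share. Cspg4 averaged 116 CPM with DMSO and 249.9 CPM with Pracinostat, with 457.8 CPM in Pracinostat replicate 3. Mbp stood at 525 CPM in Pracinostat replicate 1 (without TMM scaling), against 85.8 to 182 CPM in the other libraries. By camera, which does not weigh genes by their counts, the oligodendrocyte list gave no call (adjusted p = 0.486, direction down). Of its genes, 9 of 16 were negative, with a median of -0.42. Neutrophil markers (0.0459 and 0.0552%), dendritic cell markers (0.0882 and 0.0962%), astrocyte markers (0.0153 and 0.0144%) and glioma genes (0.038 and 0.0345%) also did not pass the exact test. Counts are of mouse genes, so the glioma list does not measure carry-over of the human xenograft cells. By camera the adjusted p was 0.53 for neutrophil and 0.486 for dendritic cell markers, and both were called higher without Pracinostat replicate 3 (0.000725 and 0.0163), where the inflammatory list had 2.06e-06. Of the 12 classes, 0 had an exact permutation p under 0.05. DMSO replicate 2 and Pracinostat replicate 1 carried collagen transcripts, with Col1a1 at 729 and 421 CPM against 12 to 32.2 CPM in the other libraries (here without TMM scaling). With both left out, 13 lists passed camera, including the inflammatory list (adjusted p = 0.0066), the monocyte-derived list (0.00123) and the endothelial list (0.0118). Newly called were the zinc-dependent deacetylases, higher (0.0445), and, lower, lysosomal (0.00793), oxidative phosphorylation (0.0066), glycolysis (0.0445), hypoxia (0.0131), lipid handling (0.0134), disease-associated (0.0435) and ribosomal protein genes (0.0066). Other splits of all 7 libraries called as many as 16 lists by the same test. The 13 calls, from a subset chosen after the data were seen, thus cannot be told apart from chance.

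**Figure D3:**
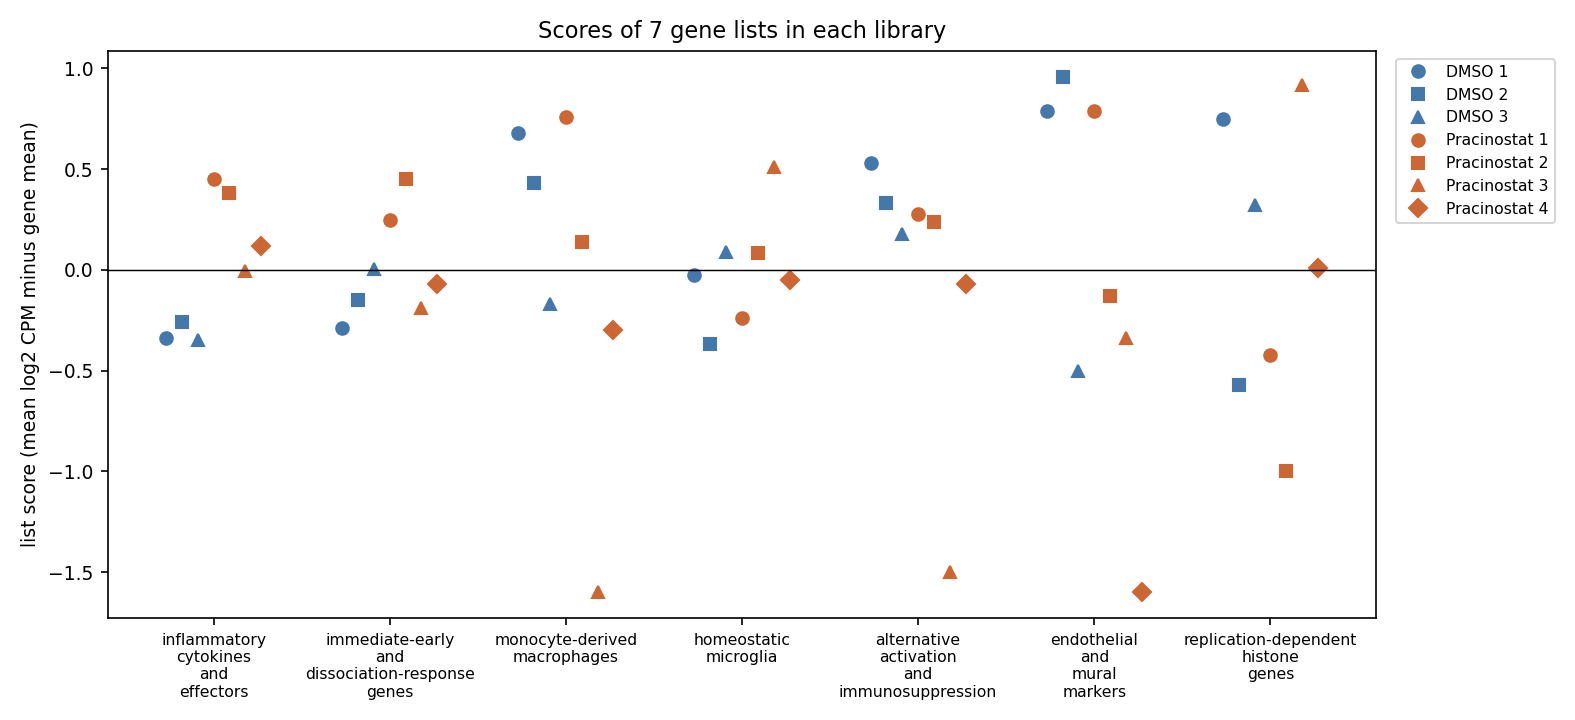
Score of 7 gene lists (mean log2 CPM minus gene mean) in each library, blue for DMSO and orange for Pracinostat. Inflammatory scores do not overlap between groups, and Pracinostat replicate 3 lies at -1.6 for the monocyte-derived list.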

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

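Of 154 values screened in the 4 Pracinostat libraries, 11 had a library whose gap to the nearest other exceeded Dixon's 95% limit as a share of the group's range, and chance flags about 1 in 20 such groups. Groups of 3 were not screened, so the DMSO libraries have no such check. Pracinostat replicate 3 held 6 of the 11. In that library Cxcl10 was at 185 CPM, against 72.7 to 86 in the other Pracinostat libraries and 37.9 to 58 with DMSO. Its Ifit3 was at 193 CPM, against 86.5 to 103 and 120 to 131. Its list scores were the lowest of the Pracinostat libraries for 4 of the lists. These were neutrophil markers (-2.83, others 1.15 to 1.51, DMSO -2.02 to 1.71) and inhibitory receptors (-0.437, others 0.0885 to 0.146, DMSO -0.138 to 0.154). The others were cholesterol biosynthesis (-0.311, others 0.0875 to 0.124, DMSO -0.078 to 0.103) and p53 targets and apoptosis (-0.252, others 0.2 to 0.242, DMSO -0.164 to -0.117). Among the Pracinostat libraries, replicate 4 had the highest Rfxap (32.6 CPM, others 17.5 to 19.8, DMSO 12.3 to 17.3). It had the lowest Tgfbr1 (460 CPM, others 496 to 503, DMSO 333 to 437) and Rgs5 (3.48 CPM, others 11 to 12.5, DMSO 8.57 to 23.8). Pracinostat replicate 1 had the highest neuron marker score (1.05, others -0.379 to -0.15, DMSO -0.368 to 0.263). Its neuron marker share was 0.00632% of counts, against 0.00235 to 0.00292% in the others and 0.00236 to 0.00594% with DMSO.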

How the results depend on the processing

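The count of 0 called genes stayed at 0 in 15 of 19 alternatives, which include other scalings, a stricter filter, limma-voom and a looser threshold, and of which the 2-fold minimum could give no other count. It was 63 with no low-count filter, of which 60 were also tested with it, 27 with DESeq2 and 4 with the replicate number as a block, a fit that also leaves out Pracinostat replicate 4. Leaving out 1 library gave 0 to 3 genes, the 3 without DMSO replicate 3. The labels do not say whether equal numbers mark paired samples. Deviations of same-numbered samples correlated at 0.045, -0.035 and 0.073, against -0.074 to 0.0511 for DMSO and Pracinostat libraries with unlike numbers. Pairing was thus not clearly seen, but these values cannot exclude it. In that block the endothelial list had an adjusted p of 0.1, the other 4 called lists stayed called, and immediate-early (0.0182) and cell cycle genes (0.045) were newly called higher, the former also without Pracinostat replicate 4 and no block (0.0221). The 5 called lists became 0 with an estimated correlation and 0 with fry. There the adjusted p was 0.948 for each of the 5 with the estimated correlation. The unadjusted p was 0.0252 for the inflammatory list and 0.266 to 0.424 for the other 4. Fry tests whether a list's genes move 1 way and not against other genes. Its adjusted p was 0.216 for the inflammatory list (unadjusted p = 0.00569) and 0.959 for the other 4. The count was 8 lists with camera on voom values and 13 without both collagen-rich libraries, 2 alternatives chosen after seeing the data. Leaving out 1 library gave 1 to 9 lists, the 1 without DMSO replicate 1 and the 9 without Pracinostat replicate 1. Over those fits the adjusted p ran from 2.06e-06 to 0.0116 for the inflammatory list, 1.28e-06 to 0.304 for the monocyte-derived list, 0.00101 to 0.284 for alternative activation, 0.000423 to 0.13 for endothelial markers and 9.12e-06 to 0.52 for replication-dependent histones. Cell cycle genes, uncalled and mostly positive with all libraries in, ran from 0.000786 to 0.865 and were called lower without Pracinostat replicate 3, against the direction in the block. Ribosomal proteins ran from 0.0285 to 0.825, called lower without DMSO replicate 2 and, at 0.0066, without both collagen-rich libraries. A change of sign was counted as a reversal only where a value passed a threshold. Immediate-early genes, at 0.948 with an estimated correlation, were also called higher with voom values (0.000527), with a stricter filter (0.0455), without DMSO replicate 3 (0.016) and without Pracinostat replicate 3 (0.000725). Signs also changed without a call in 41 of 532 list alternatives, 33 of 1732 named gene alternatives and 17 of 107 share alternatives. The count of 0 cell type and quality classes past the threshold stayed at 0 on a log2 scale and without ribosomal protein genes. With a library left out, exact tests of shares and depth cannot reach 0.05, so values alone were compared. The cause of these changes was not tested. The gene test recovered 21.9% of simulated 2-fold changes in genes with a mean log2 CPM of at least 2, so changes of that size can be missed.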

Other observations

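The predictions of the dissociation, single-library and microglia tests were written after their values were seen. Those of the mix, NF-kappaB and split tests were written before their own values were seen. All of these tests take up patterns found in the same 7 libraries, and none was among the tests fixed before the data were examined.

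A wider set of NF-kappaB target genes was drawn up after the inflammatory list had been seen, with none of its members on that list. Of its 40 genes tested, 29 had positive fold changes, with a median of 0.26. Nfkbie, another inhibitor of NF-kappaB, was at 0.88 ± 0.24, Cd83, a surface marker of activated antigen-presenting cells, at 0.94 ± 0.27 and the apoptosis inhibitor Birc3 at 0.59 ± 0.23. These genes were named after their values were seen, and none of them passed the edgeR test over all genes. The hypothesis that NF-kappaB targets were higher beyond the inflammatory list predicted a camera p under 0.05, and it was 0.00536. With an estimated correlation the p was 0.365, and it was under 0.05 in 4 of the 7 fits that left out a library. The others were 0.115 without DMSO replicate 1, 0.0716 without Pracinostat replicate 1 and 0.0889 without Pracinostat replicate 2. Without Pracinostat replicate 3 it was 6.76e-07. The set was measured in the same 7 libraries as the inflammatory list, so it is not independent support. No count over the splits is given for it, so chance stays open. Of the 40 genes, 2 are also on the dissociation list, Cd83 among them.

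Groups not described so far gave no camera call in the unblocked comparison of all 7 libraries. Disease-associated and lipid-associated genes had an adjusted p of 0.896, with Cst7 at 1.11 ± 0.40, and were called lower at 0.0435 without both collagen-rich libraries. Extracellular matrix genes had 0.486 (Timp3 -1.29 ± 0.44), angiogenic factors 0.466 (Pdgfb 0.76 ± 0.30), cell cycle genes 0.904 (29 of 39 positive), glioma genes 0.188 (Prom1 -1.82 ± 0.71, list called lower at 0.0463 without Pracinostat replicate 1), neuron markers 0.889 (called lower at 0.0455 without the same library) and ribosomal proteins 0.859. Lymphocyte, mast cell and erythrocyte markers had too few genes tested for camera, and held at most 0.0109% of the counts of any library.

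The inflammatory list was higher with Pracinostat at camera's preset correlation, a call lost with an estimated correlation (adjusted p = 0.948), and fry, which does not compare the list with other genes, gave 0.216. At the preset correlation the call did not need any 1 library, with 0.0116 as the highest adjusted p when 1 was left out. The list score was also higher in each Pracinostat library than in any DMSO library. Camera at this setting calls lists in most splits, as given below, so these fits alone cannot exclude a single library as the source. With the mix of monocyte-derived cells and microglia as a covariate, the camera p of the inflammatory list was 3.35e-08. In the same fit neutrophil (camera adjusted p of 7.89e-05), dendritic cell (0.00525), MHC class II (0.0165) and immediate-early genes (0.00458) were higher. Replication-dependent histones (2.32e-06) and cell cycle genes (0.0165) were lower. Camera at the preset correlation called at least 5 lists in 29 of 35 splits of the libraries, so this p cannot exclude that mix. A mix with other cells stays open and untested. A response to tissue dissociation cannot be told apart from a drug effect. The 25 dissociation genes outside the list had a median of 0.122 (SD 0.27 over genes) against 0.53. But their own camera p was 0.0121 in the same direction (0.366 with an estimated correlation). Most of these genes are also on the immediate-early list, so this p is not separate from that list's result. The bound that leaves this open was made stricter after the values were seen. Chance cannot be excluded, because 2 of 35 splits gave a camera p as small, the real one at 1.88e-06 and the other, which set Pracinostat replicates 1, 2 and 4 against the rest, at 2.64e-07.

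The monocyte-derived list was lower by camera with Pracinostat, a call lost with an estimated correlation (adjusted p = 0.948), and its adjusted p of 0.304 without Pracinostat replicate 3 is consistent with a difference that rests largely on that library. A candidate explanation is fewer monocyte-derived cells per microglial cell. The microglia list had a camera p of 0.0374 in the matching direction, but 0.565 with an estimated correlation, and at the preset 0.965 without the same library and 0.742 without DMSO replicate 2, so this stays open. Chance cannot be excluded, because 16 of 35 splits gave a camera p as small (real 8.89e-05, smallest other 3.72e-15).

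Endothelial and mural markers were lower by camera, a call lost with an estimated correlation (adjusted p = 0.948), and the adjusted p of 0.13 without DMSO replicate 2 is consistent with a difference that depends on few libraries. In 9 of 35 splits the camera p was as small (real 0.000898, smallest other 5.87e-07), so chance cannot be excluded. No biological explanation was tested for this list.

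Chance was not excluded for the remaining results either. A camera p as small came from 11 of 35 splits for alternative activation (real 0.00244, smallest other 7.76e-06) and from 16 of 35 for replication-dependent histones (real 0.00507, smallest other 2.67e-14). As many as 5 called lists came from 29 of 35 splits, and the highest other count was 16. As many as 661 genes with an unadjusted p under 0.05 came from 11 of 35 splits, and the highest other count was 836. On the first principal component (25.3% of variance) DMSO replicate 2 lay at -126 and DMSO replicate 3 at 75.6, with all other libraries between -6.07 and 29.7. On the second (19.2%) the DMSO libraries lay at -17.4, 45.4 and 101, above the Pracinostat libraries at -55 to -20.1.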
